A study of Homo sapiens with 6 samples.

How the data were processed

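RNA-seq was deposited for 6 libraries of HuCCT-1 cells, 3 infected with AdGFP and 3 with AdHNF4α. Per the labels' protocols, total RNA was checked for integrity, cleaned and treated with DNase, mRNA was separated and fragmented, and cDNA libraries were made. Strand handling, the dose of virus and the time after infection were not given in the sources used here. Per the submitters' processing notes, HISAT2 2.0.4, StringTie 1.3.3b and edgeR were used with the GRCh38 (hg38) human genome. The role of each tool, the counting options and the annotation release were not given in the sources used here. 1 deposited table held, per the file headers, raw read counts and FPKM values of each library for 50868 Ensembl genes. The deposited FPKM equalled the count divided by the column total and by a gene length, up to a constant, with a length that was the same in each FPKM column used, so FPKM held no information beyond the counts. Of the gene IDs, 98.51% were found in GENCODE release 29, which was used for GC content and exon overlap. 1 AdHNF4α column carried a replicate number that differed from the labels; its counts were used as a library of that group without a number. Its FPKM column, 1 column of values, was not used; FPKM of that library was computed from its counts by the same formula, without 627 genes that had a count in no other library and so no length.

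Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, which here meant 0.546 CPM in at least 3 libraries, and a total of 15), scaled by TMM, and fitted with glmQLFit (robust) on infection. Calls used glmQLFTest with Benjamini-Hochberg adjustment over the 15595 genes tested, at an adjusted p under 0.05. CPM are scaled by TMM, except that shares of counts use column totals. Standard errors of log2 fold changes come from the same fit. The common dispersion was 0.0175, a biological coefficient of variation of 13.23%. Total counts of 16489592 to 19741474 per library gave a limit of 0.152 to 0.182 CPM for 3 counts. Ratios of genes with fewer than 10 counts in the lower group were taken from summed counts with an exact 95% interval, which covers counting error only.

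31 gene lists with 727 entries, the tests, the naming rule and most alternatives were fixed before the data were examined; 12 entries had no symbol in the table. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over 30 lists. Histone, mitochondrial, ribosomal protein and immediate early lists were RNA quality and handling checks. Named genes were HNF4A, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, with a mean of at least 1 CPM and at least 10 counts in the lower group, up to 4 called genes with fewer counts, and up to 3 members per list by smallest adjusted p. Clones, antisense RNAs, microRNAs, snoRNAs and pseudogenes were left out of the largest changes. Some genes that this rule picked are not reported here. Other members that the text names were chosen after their values were seen.

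Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors or library size alone in edgeR, no or a stricter count filter (5 CPM in 3 libraries), no robust estimation, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with values of at least 1 in 3 libraries, no FPKM filter, a threshold of 0.01, and each library left out in turn. A correction of each library's trend with GC content and length, and list adjustment without the 4 RNA quality and handling lists, were added after seeing the data, as were family tests without pseudogenes and with near-identical pairs counted once. GC content was known for 99.5% of tested genes.

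The edgeR steps were tested on simulated counts with 200 genes changed, drawn for this comparison and fitted over 15371 genes. With dispersions on the trend, 6.25% of 1.25-fold, 43.75% of 1.5-fold, 89.36% of 2-fold and 100% of 4-fold changes were recovered, and 10 of 125 calls were false. With dispersions estimated gene by gene, 15 of 116 calls were false. Both shares were above the nominal 5%, so some calls of the text may be false. Both simulations called far fewer genes than the 8699 called in the data, so the recovered and false shares may differ there. The trended simulation was made the first of these after the second result was seen. In a simulation of lists over 15369 genes with independent errors, 0 of 29 unchanged lists were called; real libraries have correlated errors.

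Of 103 named genes, 7 shared at least 10% of their exonic bases with another tested gene by bedtools 2.31.1. These were CD68, SLCO1B3, SERPINA3, VIL1, FDPS, RPS25 and ALDH6A1, the last 4 with a gene on the opposite strand, from which reads cannot be told without strand information. Histone genes, MT-ATP6, DEFB103A and DEFB4A have near-identical copies that can share reads.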

Results

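RNA-seq gene counts were examined in HuCCT-1 cells, an established human cholangiocarcinoma (bile duct cancer) line, after infection with an adenovirus that carried GFP (AdGFP) or the liver transcription factor HNF4α (AdHNF4α). Each group had 3 libraries. The table listed 50868 genes, of which 28140 had a count in at least 1 library. Total counts per library ranged from 16489592 to 19741474, and between 22124 and 22595 genes had a count in each. Libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.206 to 12.57 over genes, against 114 to 125.7 between groups. None was therefore treated as a copy of another. The first principal component of log2 CPM held 73.32% of the variance and separated the groups. The labels did not say whether the 3 libraries of a group came from separate cultures, so p-values measured the spread between these libraries, which may be technical.

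HNF4A, which encodes the overexpressed factor, was examined first because it checks the labels. Its counts were 53, 62 and 66 in the AdGFP libraries and 120363, 108017 and 88772 in the AdHNF4α libraries. Mean expression rose from 3.33 ± 0.563 CPM to 5777 ± 418 CPM (SD, n = 3 per group), a log2 fold change of 10.76 ± 0.13 (SE). HNF4A took between 0.538% and 0.610% of all counts in the AdHNF4α libraries, with exact Clopper-Pearson 95% intervals of 0.535 to 0.542% at the lowest and 0.606 to 0.613% at the highest. Those intervals cover counting error only. The gene (ENSG00000101076) lies on chromosome 20 from 44355700 to 44434596 on the plus strand of GRCh38. The adjusted p was 2.23e-09 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Reads of the transgene and of the endogenous gene were counted together.

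The series asked which genes differed between the infections. Gene expression differed across much of the transcriptome, in both directions. Among 15595 genes tested, 4342 were higher and 4357 were lower in AdHNF4α, together 55.78% of those tested. At least 2-fold changes numbered 1099 higher and 1312 lower, and at least 4-fold changes 241 and 282. The balance between directions rests on TMM scaling, which centres the changes near 0; with library size alone 4658 were higher and 4067 lower, and by limma on log2(FPKM + 1) 4007 and 3290. Many calls were small, since 3738 of the 8699 were under 1.5-fold. The 3 libraries of one group lay wholly above those of the other for 9955 genes (63.83%), where 10% is given by chance. All counts used the edgeR quasi-likelihood test at an adjusted p under 0.05. The numbers of at least 2-fold calls depended on the scale and filter, with 408 higher and 375 lower by limma on log2(FPKM + 1), and 619 and 787 with at least 5 CPM required in 3 libraries.

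Among genes with at least 10 counts in the lower group, MUC13 and TNFSF18 rose most apart from HNF4A. MUC13, a membrane mucin of the gut lining, rose from 0.455 ± 0.166 to 21.2 ± 0.985 CPM (SD, n = 3), a 45.9-fold change, and TNFSF18, a tumour necrosis factor family ligand, from 2.71 ± 0.996 to 107 ± 5.93 CPM. GPD1, a glycerol-3-phosphate dehydrogenase, rose 36.7-fold, the protease gene KLK7 31.2-fold, the endoplasmic reticulum oxidase gene ERO1B 28.8-fold and the cytokine gene IL24 24.5-fold. GPD1, KLK7 and IL24 had only 10, 11 and 17 counts over the AdGFP libraries, so their folds are imprecise. The SE of the KLK7 log2 fold change was 0.46. AKAP12, a kinase anchoring protein gene with far more counts, rose from 58.9 ± 2.11 to 1186 ± 32.4 CPM, and PDZK1, a scaffold protein gene of epithelial transporters, rose 19.4-fold. Some genes had few or almost no counts in AdGFP. MOGAT3, an acyltransferase gene of triglyceride synthesis, had 5 counts over the AdGFP libraries and 845 over the AdHNF4α libraries, a ratio per total count of 173.4 (95% counting interval 74.03 to 535.5). The cytochrome P450 gene CYP1A2 went from 3 to 477 counts, a ratio of 163.2 (55.5 to 794). VIL1, which encodes the brush border protein villin, went from 3 to 390 counts, a ratio of 133.4 (45.31 to 649.7). The beta-defensin gene DEFB103A had 9 and 219 counts, a ratio of 24.97 (12.92 to 55.34), and is uncertain because reads cannot be told from those of its near-identical copy DEFB103B. VIL1 shared 44.0% of its exonic bases with a gene on the opposite strand. Adjusted p of these 12 genes by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment lay between 1.69e-09 for AKAP12 and 6.996e-05 for DEFB103A.

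CLDN2, NKD1, WNT11 and AXIN2 were among the genes that fell most. CLDN2, a pore-forming claudin gene, fell from 32.1 ± 1.84 to 0.482 ± 0.237 CPM (SD, n = 3), a 64.5-fold change. NKD1 and AXIN2, feedback inhibitors of WNT signalling, fell 25.2-fold and 20.5-fold, and the ligand gene WNT11 fell 24.3-fold. The transcription factor gene ATOH8 fell 27.5-fold, a fold that rests on 10 counts over the AdHNF4α libraries (log2 SE 0.37). ID1, an inhibitor of helix-loop-helix factors and a BMP target, fell from 309 ± 13.2 to 18.8 ± 0.576 CPM. The chemokine genes CCL2 and CXCL6 each fell 14.9-fold, CCL2 from 71.7 ± 3.31 to 4.79 ± 0.603 CPM. Adjusted p for these 8 genes ranged from 1.84e-09 for ID1 to 8.17e-06 for ATOH8 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

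**Figure D1:**
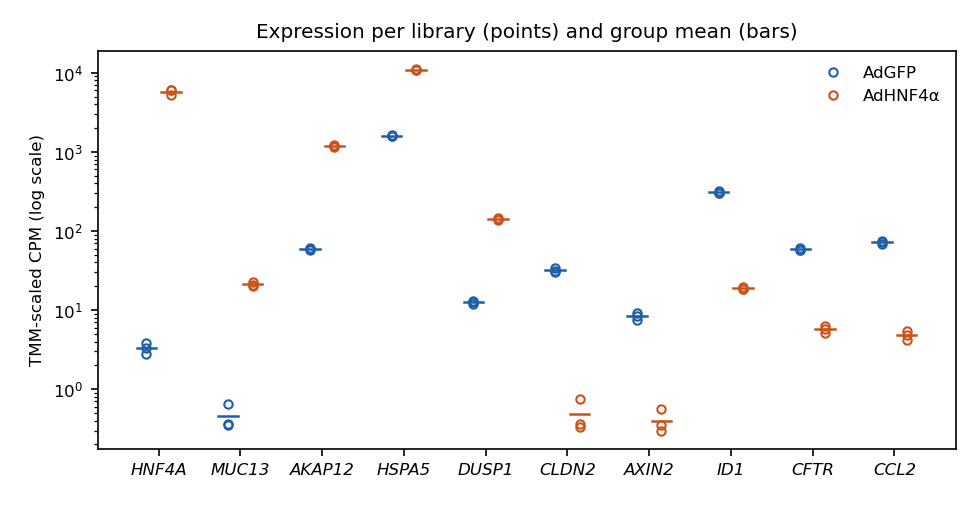
TMM-scaled CPM on a log axis for 10 named genes. Circles are the 3 libraries of each group and short bars are group means; in each gene the groups lie apart, as for HNF4A with means of 3.33 and 5777 CPM.

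Most genes of the unfolded protein response list rose. Of the 24 fixed unfolded protein response genes, 20 rose, 1 fell and 3 did not pass the test, with a median log2 fold change of 1.67. HSPA5, the gene of the chief chaperone of that compartment (ENSG00000044574), rose from 1596 ± 19.1 to 10976 ± 186 CPM (SD, n = 3), a log2 fold change of 2.78 ± 0.04 (SE). The disulfide isomerase gene PDIA4 rose 3.63-fold and CRELD2, another folding factor gene, 4.84-fold. ATF4, a transcription factor gene of the integrated stress response, fell by 0.54 on the log2 scale. CHAC1, TRIB3 and CANX had log2 fold changes of -0.65, 0.42 and 0.21 that did not pass the test; these and ATF4 were picked after their values were seen, and CHAC1 had 1 library that stood apart from its group mates. The list was called higher by camera with Benjamini-Hochberg adjustment (adjusted p = 9.8e-09), and had adjusted p = 0.0667 with an estimated correlation.

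Lists of intestinal and of amino acid metabolism genes were also called higher. Of 27 intestinal epithelial and brush border genes, only 8 had enough counts to be tested, of which 5 rose and 2 fell. The 19 untested ones had at most 22 counts in a library, and 8 of them had none in any library. Without a count filter 19 members were tested, of which 8 rose and 3 fell. MUC13 and VIL1 stood among the rises, together with EPS8L3, an actin regulator gene that went from 11.8 ± 0.705 to 52.5 ± 3.24 CPM (SD, n = 3). Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.0337, and adjusted p = 0.19 with an estimated correlation. Of 34 amino acid and urea metabolism genes, 16 were tested, of which 9 rose and 1 fell. The 18 untested ones had at most 12 counts in a library. ALDH6A1, of valine breakdown, rose 2.41-fold and CTH, of cysteine synthesis, 2.31-fold, while the urea cycle gene ASS1 fell 2.21-fold. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.0114, and adjusted p = 0.17 with an estimated correlation. The intestinal call was lost with ranks, at adjusted p = 0.0648 by camera with Benjamini-Hochberg adjustment. With the stricter count filter the intestinal and amino acid lists had camera adjusted p of 0.0975 and 0.0574 after Benjamini-Hochberg adjustment.

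Markers of the bile duct epithelium fell. Of 22 tested cholangiocyte and biliary epithelial markers, 15 fell, 1 rose and 6 did not pass the test, with a median log2 fold change of -0.97. CFTR, the chloride channel gene, fell from 58.6 ± 1.97 to 5.77 ± 0.574 CPM (SD, n = 3). The transcription factor gene SOX4 fell 5.30-fold and BICC1, an RNA-binding protein gene, 4.64-fold. The keratin genes KRT7 and KRT19, picked after their values were seen, fell by 0.72 and 1.05 on the log2 scale. The list was called lower by camera with Benjamini-Hochberg adjustment (adjusted p = 7.97e-05), with adjusted p = 0.124 with an estimated correlation. CLDN4, another member, had counts of 3425, 3383 and 9 in AdGFP and 10, 2218 and 4 in AdHNF4α, a spread within groups that left its change undetermined.

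**Figure D2:**
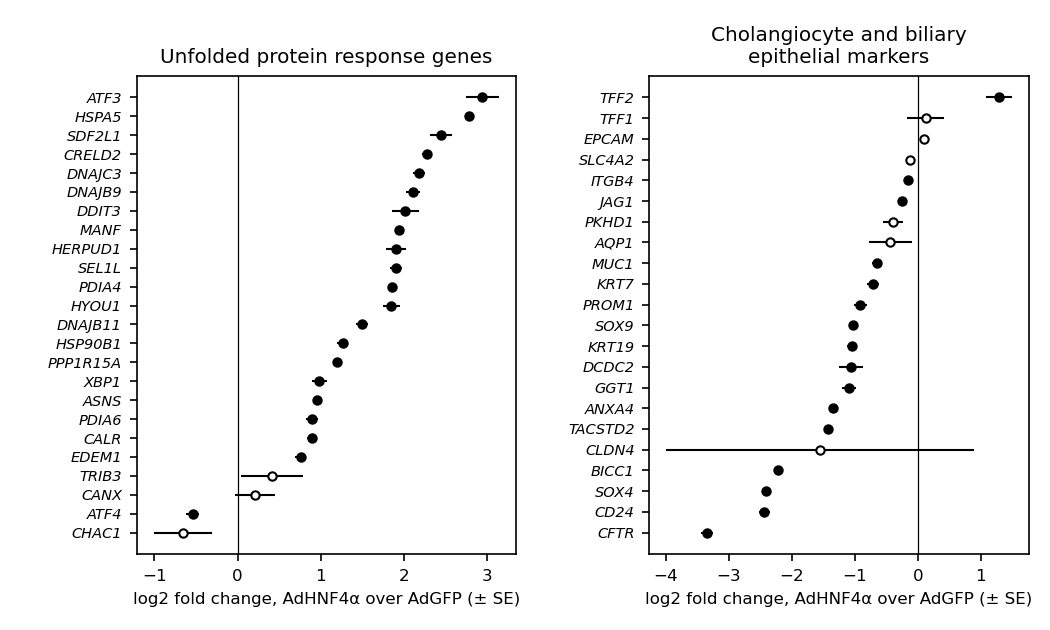
Log2 fold change, AdHNF4α over AdGFP, with its SE for the tested members of both lists; filled points passed the edgeR test at an adjusted p under 0.05. Of the unfolded protein response genes 20 of 24 lie above 0 and passed, and of the biliary markers 15 of 22 lie below 0 and passed.

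Cell cycle genes were mostly lower. Of 36 cell cycle and proliferation genes, 24 fell and 3 rose. TOP2A, the mitotic topoisomerase gene, fell from 504 ± 17.4 to 185 ± 10.3 CPM (SD, n = 3), and the mitotic kinesin gene KIF20A fell 3.25-fold. CDC6, which loads the replicative helicase, rose 4.57-fold; CDC25A and CCNE1, regulators of entry into S phase picked after their values were seen, rose by log2 fold changes of 1.82 and 0.61. Camera with Benjamini-Hochberg adjustment called the list lower (adjusted p = 0.00011), with adjusted p = 0.124 with an estimated correlation.

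Glycolysis and cholesterol synthesis genes fell. Of 20 glycolysis genes, 17 fell and 1 rose. PGK1 fell from 1674 ± 10.1 to 668 ± 14.2 CPM (SD, n = 3), PFKL 2.41-fold and PFKFB4, which makes an activator of phosphofructokinase, 5.35-fold. The list had adjusted p = 7.08e-05 by camera with Benjamini-Hochberg adjustment and adjusted p = 0.19 with an estimated correlation. Of 23 cholesterol synthesis genes, 18 fell and 1 rose. LSS, the lanosterol synthase gene, fell 2.64-fold, FDFT1 1.95-fold and FDPS 1.89-fold. The list had adjusted p = 0.000618 by camera with Benjamini-Hochberg adjustment and adjusted p = 0.124 with an estimated correlation. Of 24 tested genes of fatty acid oxidation and ketogenesis, 10 rose and 4 fell. The lipid droplet gene PLIN2 rose 5.75-fold and the carnitine carrier gene SLC25A20 4.86-fold, but the list was not called (camera, Benjamini-Hochberg adjusted p = 0.0913). Of 10 tested gluconeogenesis and glycogen genes, 2 rose and 5 fell, with GCKR, the glucokinase regulator gene, up 4.21-fold and PCK2 up 1.87-fold, and the list was not called (camera, Benjamini-Hochberg adjusted p = 0.566).

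Most of the listed hepatocyte genes had too few counts to be tested. Only 4 of 23 hepatocyte plasma protein genes had enough counts to be tested, and no untested one exceeded 16 counts in a library. RBP4, the retinol carrier gene, rose from 0.652 ± 0.169 to 5.21 ± 0.408 CPM (SD, n = 3), SERPINA1 rose 1.14-fold and SERPINA3 went from 10.6 ± 2.78 to 5.34 ± 1.29 CPM and passed the test, a call lost with the replicate number as a block, which rests on 2 pairs. The SERPINA1 call was lost without AdGFP replicate 1, AdGFP replicate 3 or AdHNF4α replicate 2, at log2 fold changes of 0.16, 0.18 and 0.15. With 4 tested members the list was too short for camera. Of the coagulation and fibrinolysis factors made by liver, 5 of 22 were tested and PROC, the protein C gene, fell 2.72-fold. Of the apolipoprotein and lipoprotein assembly genes, 5 of 20 were tested and 2 fell. APOM fell 1.45-fold, a call lost in 11 of 17 other settings. Of 11 tested genes of bile acid synthesis and hepatic transport, 2 rose and 4 fell; FGF19, a hormone that represses bile acid synthesis, fell 13.7-fold, ABCC3 fell 1.63-fold and SLCO1B3 rose 1.63-fold. SERPINA3 and SLCO1B3 are uncertain, since they shared 31.8% and 54.5% of their exonic bases with another gene on the same strand. Of 11 tested drug metabolism enzymes, 3 rose and 5 fell, among them CYP1A2 and CES2 (2.23-fold) higher and EPHX1 1.86-fold lower. Of 13 tested liver transcription factors other than HNF4A, 3 rose and 5 fell, with FOXA1 down 3.21-fold and RXRA 1.63-fold. None of these lists was called, with adjusted p from 0.221 for apolipoproteins to 0.723 for transcription factors by camera with Benjamini-Hochberg adjustment. At these depths 3 counts correspond to between 0.152 and 0.182 CPM, so lower levels were not detectable.

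Signalling lists moved in both directions. Of 13 tested WNT beta-catenin target genes, 6 fell and 3 rose, with CD44 down 2.05-fold beside NKD1 and AXIN2 (camera, Benjamini-Hochberg adjusted p = 0.264). Of 21 YAP/TAZ target genes, 9 rose and 5 fell, including GADD45A up 5.94-fold, CCN1 up 2.46-fold and AXL up 2.48-fold (camera, Benjamini-Hochberg adjusted p = 0.199). Of 11 NOTCH pathway genes, 3 rose and 4 fell, with the modifier gene LFNG down 9.87-fold, the target gene HES1 down 2.38-fold and NOTCH1 up 2.27-fold (camera, Benjamini-Hochberg adjusted p = 0.723). Of 28 NF-kB and inflammatory genes, 11 rose and 10 fell, with IL1A up 3.93-fold and ICAM1 up 2.91-fold beside the fall of CCL2 (camera, Benjamini-Hochberg adjusted p = 0.755). Of 25 interferon-stimulated genes, 4 rose and 12 fell, with IFI44L down 7.97-fold, IFI44 down 2.99-fold and ISG20 up 3.12-fold (camera, Benjamini-Hochberg adjusted p = 0.0888). Of 24 p53 target genes, 12 rose and 5 fell, with AEN up 3.01-fold, PLK3 3.25-fold and SESN2 2.18-fold (camera, Benjamini-Hochberg adjusted p = 0.054). Without AdHNF4α replicate 1 or 2 the p53 list was called, at camera adjusted p of 0.0376 and 0.0449 after Benjamini-Hochberg adjustment. Of 17 hypoxia target genes, 2 rose and 6 fell, with EGLN3 down 4.01-fold, PDK1 down 2.12-fold and STC2 up 3.30-fold (camera, Benjamini-Hochberg adjusted p = 0.177).

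Junction and mesenchymal genes were also mixed. Of 28 epithelial junction genes, 10 rose and 13 fell, with CLDN1 up 1.81-fold, JUP, the plakoglobin gene, down 1.96-fold, and CLDN2 down as above (camera, Benjamini-Hochberg adjusted p = 0.723). Of 21 mesenchymal and EMT genes, 3 rose and 7 fell. The receptor gene AXL rose, while TGFBI fell from 1520 ± 86.6 to 512 ± 47.0 CPM (SD, n = 3). The list was not called (camera, Benjamini-Hochberg adjusted p = 0.875).

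Markers of other cell types were mostly low, and some moved with the infection. Of 6 tested fibroblast markers 5 fell, with FBLN1 down 1.58-fold, LUM 2.14-fold and C1S 3.14-fold (camera, Benjamini-Hochberg adjusted p = 0.0279, and adjusted p = 0.19 with an estimated correlation). Of 5 tested leukocyte markers 3 rose and 1 fell, with CD68 up 3.31-fold, CD79A up 2.33-fold and CD14 down 2.07-fold (camera, Benjamini-Hochberg adjusted p = 0.558). CD68 shared 81.7% of its exonic bases with another tested gene and is uncertain. Of 5 tested endothelial markers 2 rose and 2 fell, with PECAM1 down 3.54-fold, VWF down 3.20-fold and ESAM up 1.37-fold (camera, Benjamini-Hochberg adjusted p = 0.87). The ESAM call was lost without AdHNF4α replicate 2, at a log2 fold change of 0.38, and the VWF call with the replicate number as a block.

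Genes that track RNA content and handling fell in part, alongside the lists above. Mitochondrially encoded genes took 7.26 to 7.57% of counts in AdGFP and 6.23 to 6.56% in AdHNF4α. Of 13 such genes 10 fell and 1 rose. MT-CO3 fell from 4804 ± 149 to 1701 ± 68.6 CPM (SD, n = 3) and MT-CYB 1.78-fold, while MT-ATP6, whose annotated end adjoins MT-CO3, rose 2.62-fold. The list had adjusted p = 0.0114 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.485 with an estimated correlation. Of 39 cytosolic ribosomal protein genes 23 fell and none rose, with RPS14 down 1.63-fold, RPL15 1.56-fold and RPS25 1.47-fold (camera, Benjamini-Hochberg adjusted p = 0.000547, and adjusted p = 0.301 with an estimated correlation). Of 9 tested replication-dependent histone genes 7 fell, with H3C10 down 4.18-fold, H2BC12 2.42-fold and H2BC5 1.74-fold (camera, Benjamini-Hochberg adjusted p = 0.00246, and adjusted p = 0.139 with an estimated correlation). Of 14 immediate early stress genes 4 rose and 4 fell, with DUSP1 up 11.3-fold, HMOX1 up 3.10-fold and EGR1 down 2.26-fold (camera, Benjamini-Hochberg adjusted p = 0.723).

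**Figure D3:**
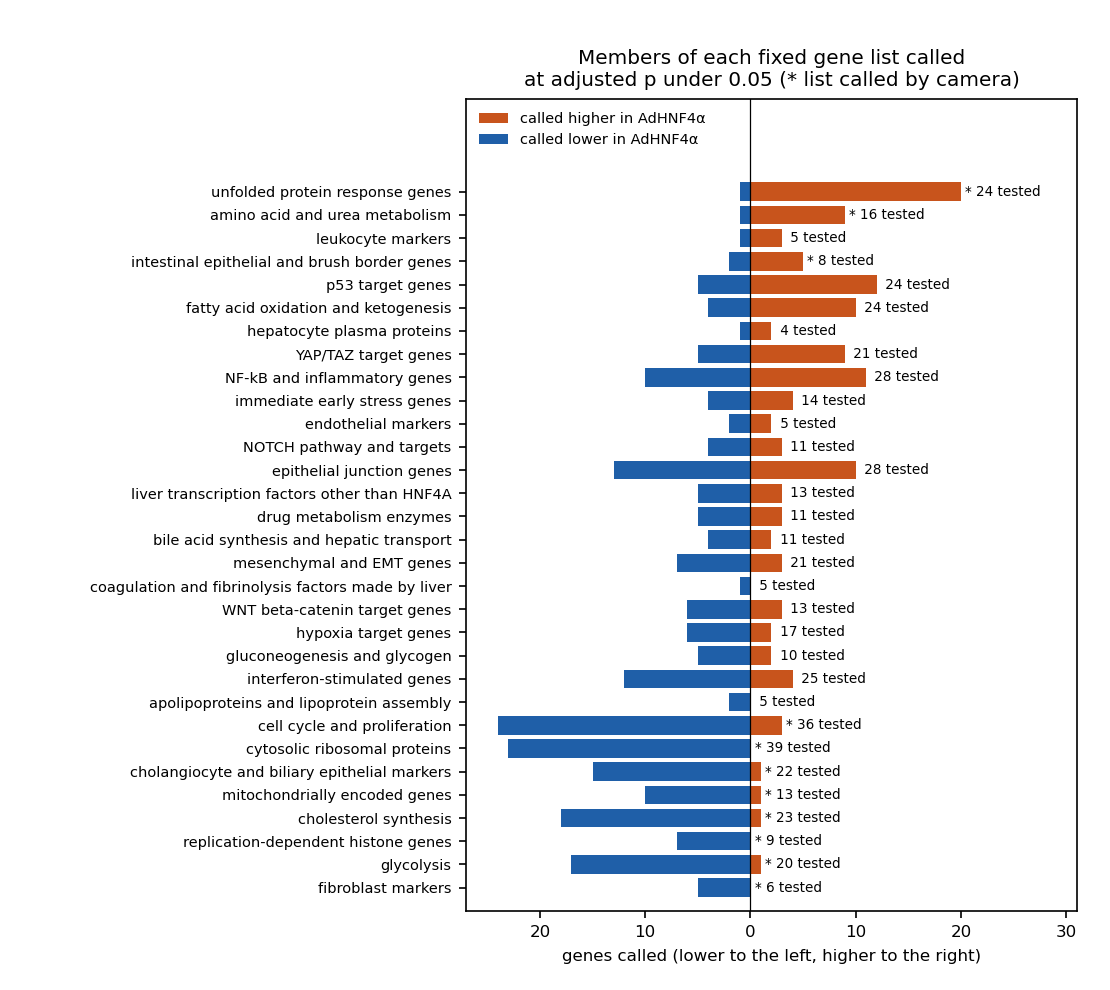
Genes called higher (right) and lower (left) in AdHNF4α in each of the 31 gene lists, by the edgeR test at an adjusted p under 0.05; the number tested stands beside each bar. A star marks the 3 lists called higher and the 8 called lower by camera with its preset correlation.

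In all, camera called 3 of the 30 lists it tested higher and 8 lower. With an estimated correlation camera called 0 lists, while 7 had an unadjusted p under 0.05 and the fry rotation test called 10 higher and 17 lower. For the unfolded protein response, intestinal, amino acid, cholesterol synthesis, fibroblast and histone lists the estimate lay below the preset, from -0.156 to 0.000559. A higher correlation is therefore not why these calls were lost. For the biliary, cell cycle, glycolysis, mitochondrial and ribosomal protein lists it lay above, from 0.014 to 0.453. Other splits of the 6 libraries into 3 and 3 each called between 1 and 8 lists with the preset correlation, but at most 2 genes. Each of these splits still set 2 libraries of one infection against 1. Single list calls should be read with their member counts. Adjusted over the list alone, member counts were as given above except for 16 lower biliary markers, 2 higher and 19 lower cholesterol synthesis genes, and 1 lower apolipoprotein gene.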

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

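The GC content and length correction and the list adjustment without RNA quality lists were chosen after seeing the data. Counts of higher and lower genes stayed within 1.5 times of 4342 and 4357 in each setting. With a library left out they ranged from 3883 to 4185 and from 3980 to 4182, at least 2-fold calls from 1101 to 1153 and from 1326 to 1359, and lists from 3 to 4 higher with 8 lower throughout. Calls of at least 2-fold numbered 619 higher and 787 lower with the stricter filter, which tested 11611 genes, 408 and 375 by limma on log2(FPKM + 1), 731 and 700 on log2(FPKM + 0.1), and 406 and 374 on log2(FPKM + 1) without a filter. The added pseudocount shrinks changes of low genes, and other causes were not tested. Of the 8699 calls, the replicate block, which rests on 4 of the 6 libraries, kept 76.37% in the same direction, the lowest share, limma on log2(FPKM + 0.1) 78.88%, on log2(FPKM + 1) 79.04%, the stricter filter 81.29% and DESeq2 89.14%; no setting called a gene in the opposite direction. The HNF4A log2 fold change ranged from 8.33 to 10.95, lowest on log2(FPKM + 1). Lists called numbered 0 higher and 0 lower with an estimated correlation, 10 and 17 by fry, 1 higher with the stricter filter, where 25 lists were long enough, and 5 lower without the 4 RNA quality lists. The intestinal list was also not called with the replicate block or the GC content and length correction, at Benjamini-Hochberg adjusted p of 0.103 and 0.0504 by camera. The drug metabolism list, lower and not called by camera, was called higher by fry (Benjamini-Hochberg adjusted p = 0.0232); fry asks another question, and the cause was not tested. Of 103 named genes, 98 kept their call in each setting that tested them; APOM, SERPINA1, SERPINA3, VWF and ESAM lost it in 1 or more.

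The replicate numbers were shared by 2 pairs only. Their deviations correlated at 0.0202 and 0.0406, against -0.0506 to 0.0392 for other combinations of an AdGFP and an AdHNF4α library. All these values are small, and whether the numbers pair the libraries stays undecided. The block fit compares within these 2 pairs, so the other 2 libraries do not enter the change and precision is lost. With the replicate block 3512 genes were higher and 3501 lower, 996 and 1201 at least 2-fold, 2 lists higher and 8 lower, and the HNF4A log2 fold change was 10.95. The calls of APOM, SERPINA3 and VWF were lost with it, at log2 fold changes of -0.33, -1.24 and -1.50. Counts were too low to test most hepatocyte genes. In simulation 43.75% of 1.5-fold and 89.36% of 2-fold changes were recovered and nearly all smaller ones were missed. The simulation called far fewer genes than the data, so these shares cannot be carried over to the data. There, 3738 of the 8699 calls were under 1.5-fold.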

Other observations

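Gene families that the fixed lists covered in part or not at all were examined after their values were seen, in 28 Fisher's exact tests of 14 families with Benjamini-Hochberg adjustment over all 28. Of 25 genes with SEC symbols, mostly of the translocon and of COPII coats, which move proteins into and out of the endoplasmic reticulum, 18 were higher (adjusted p = 7.9e-05), such as SEC23B and SEC24D with log2 fold changes of 1.19 and 1.18. 2 of the 18 are pseudogenes that may take reads of their parent genes; without pseudogenes 16 of 23 were higher (Fisher's exact test, adjusted p = 0.000331). Of 18 cytosolic aminoacyl-tRNA synthetase genes 14 were higher (Fisher's exact test, adjusted p = 0.000143), of 38 DnaJ co-chaperone genes 22 (adjusted p = 0.000747) and of 22 heat shock protein genes 12 (adjusted p = 0.0229), although the cytosolic chaperone gene HSPA8 was lower at -0.93. Beta-defensin and small proline-rich protein genes were higher in 7 of 9 (Fisher's exact test, adjusted p = 0.0107), with SPRR2D at 4.06, while DEFB1 was lower at -2.20. DEFB4A and DEFB4B, and DEFB103A and DEFB103B, are near-identical pairs whose reads cannot be told apart; with each pair counted once 5 of 7 were higher (Fisher's exact test, adjusted p = 0.0499). Protein disulfide isomerase and ERO1 oxidase genes were higher in 7 and lower in 2 of 10 (Fisher's exact test, adjusted p = 0.0229). These families overlap in part with the unfolded protein response list, and members of a family are not independent. Adjustment covered the 28 tests but not the choice of families after their values were seen.

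Mucin genes were lower in 7 and higher in 3 of 11 (Fisher's exact test, adjusted p = 0.0343), with the gel-forming mucin genes MUC6, MUC5B and MUC5AC at log2 fold changes of -3.36, -2.85 and -1.52. The higher ones were MUC13, MUC21 at 4.11, and MUC17, which had a mean of 0 CPM in AdGFP and 2.877 CPM in AdHNF4α. Frizzled receptor genes were lower in 6 of 8 (Fisher's exact test, adjusted p = 0.0229), with FZD1 at -1.29 and FZD7 at -0.80. The 3 tested ID genes were lower (Fisher's exact test, adjusted p = 0.047), with ID2 at -1.25; with library size alone 2 of them passed the test. Of 78 mitochondrial ribosomal protein genes 7 were lower and 30 higher, fewer lower calls than among other genes (Fisher's exact test, adjusted p = 0.000451). Keratin, proteasome and glucose transporter families passed neither test.

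Counts of some genes stood apart in 1 library in a way the groups do not follow. Of 9914 genes with a mean of at least 10 CPM, 257 (2.59%) had a library that differed by more than 1 on the log2 scale from group mates lying within 0.4 of each other. CLDN4 had 178.5, 182 and 0.530 CPM in AdGFP and 0.503, 122.8 and 0.239 CPM in AdHNF4α, and MKI67 had 573.5, 507 and 163.1 CPM in AdGFP. Of the 257 genes 241 were not called in the comparison. A gap of more than 1 on the log2 scale between 3 libraries and the remaining 3 was met by 628 genes in the real grouping and by 1 to 3 genes in each other grouping. The other groupings put both infections on each side, so few genes could meet it there once the infections differed.

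Among the tests that follow, those of GC content and length, the S phase genes, the mitochondrial genes and the HNF4α explanation were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 8699 calls, 1 as many as 2411 calls of at least 2-fold, and 1 as many as 11 lists called by camera. The highest other splits gave 2 calls, 2 calls of at least 2-fold and 8 lists. The other splits set 2 libraries of one infection and 1 of the other against the reverse. They keep part of the group difference and also put both infections on each side. That widens the spread within sides, so few gene calls were likely from them once the infections differed. With 10 splits the share is never under 0.1, too few for a share under 0.05.

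The rise of 20 of 24 unfolded protein response genes is the pattern with the smallest list p. After each library's trend with GC content and length was removed, 20 members were still called higher, with a median log2 fold change of 1.61, which argues against that bias as the whole cause. With each library left out in turn, at least 20 members were called higher, which argues against a single deviating library. In 20 members all AdHNF4α libraries lay above all AdGFP libraries. That nearly follows from their being called higher, and the groups lay apart in 1 or the other direction for 63.83% of tested genes. It therefore points to no cause. Expression of HNF4α may underlie the rise. That hypothesis cannot be told apart from a response to making a protein in large amount, because the amount of GFP made by the control vector was not measured here and the design has no series of HNF4α amounts.

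Replication-dependent histone genes were lower in 23 of 30 tested members of the whole family, with a median log2 fold change of -0.96. A median of -0.95 after the GC content and length correction argues against that bias. Since mRNAs of this family mostly lack a poly(A) tail, less carry-over of such RNA through mRNA selection could lower them. Whether the counted reads came from transcripts with a tail was not examined. The 6 other tested RNAs without a tail had a median of -0.93 with an SE of 0.547, 2 lower and 1 higher, too few to decide; the rule that says so was made stricter after this result was seen. Fewer cells in S phase is a hypothesis that stays open, since MCM2 to MCM7, PCNA, RRM2 and TYMS had a median of -0.64 and 7 of these 9 were lower. They are part of the cell cycle list, of which 24 genes fell and 3 rose, so they are no separate check. CDC6, CDC25A and CCNE1 of that list were higher, and whether their rise bears on the number of cells in S phase was not tested.

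MT-ATP6 was higher while MT-CO3, its neighbour on the mitochondrial genome, was lower. Reads shared with the nuclear copy MTATP6P1 would leave the sum of both at or below 0, but that sum had a log2 fold change of 0.61 ± 0.0812 (SE), which argues against this as the whole cause. MTATP6P1 itself had 301.6, 314.6 and 9.85 CPM in AdHNF4α, the last in the unnumbered library. Reads that moved between neighbouring genes in counting may explain part of the pattern. The sum of MT-ATP8, MT-ATP6, MTATP6P1 and MT-CO3 had a log2 fold change of -0.74. It lay within the range of -0.97 to 0.072 of the 10 other mitochondrial mRNAs, a wide range that makes the test weak. Mean MT-ATP6 rose from 713 to 1867 CPM while MT-CO3 fell from 4804 to 1701 CPM. Reads moved to MT-ATP6 would therefore cover only part of the MT-CO3 fall. No biological explanation was tested.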
